A study of Mus musculus with 18 samples.

How the data were processed

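Total RNA of 18 cultures of mouse cortical neural progenitor cells was sequenced by the study. Per the labels, virus-containing medium was removed 14 h after infection, cells were harvested at 72 h, RNA integrity numbers were at least 9.0, and libraries were made with the Illumina TruSeq Stranded Total RNA kit. The authors aligned reads with STAR to the mm10 mouse genome, per the labels; versions, the quantification tool and the gene annotation are not given there. The deposited table holds abundances in TPM for 55573 genes, made by the authors, and each library's values sum to 1000000. TPM keep no read totals, so depth is unknown, no counting interval or detection limit can be given, and a rise in some genes lowers the TPM of all others. Gene IDs were looked up in GENCODE M21: 55480 matched without the version and 55094 with it. For 27 genes the table's names had become dates and were restored by ID, and 122 names occur more than once, so genes were handled by ID.

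The groups are those of the labels, with 6 libraries each. Values were transformed to log2(TPM + 1), and genes with at least 1 TPM in at least 6 libraries were tested, 15216 in all. A model with 3 group means over all 18 libraries was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend. Log2 differences with standard errors (SE) are from that fit, and adjusted p values follow Benjamini and Hochberg with a threshold of 0.05. Upf2 and Trp53, and the summed TPM of marker lists with under 5 tested members, were compared by exact two-sided permutation tests of 6 against 6 libraries, which cannot give a p below 0.0022. The 6 tests of Upf2 and Trp53 were adjusted together, and so were those of the marker sums and the mitochondrial share. Gene lists, 21 in number, were fixed before the data were examined, as were the groups, the tests, the alternative settings and the choice of named genes. Lists with at least 5 tested members, 18 in number, were tested with camera, two-sided, with a preset correlation of 0.01 and with one estimated per list, adjusted over all lists and the 3 comparisons. The lists were written from general knowledge and none was taken from these libraries. List medians are over tested members.

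The named genes are Upf2 and Trp53; in each comparison the 8 largest rises and 8 largest falls among changed genes whose groups do not overlap and whose higher group averages at least 5 TPM; up to 4 members of each list with the smallest adjusted p; and Cdkn1a, Mdm2, Ccng1, Eda2r, Gas5, Gadd45b, Atf4, Ddit3, Smg1, Smg5, Upf3b, Mki67, Ccnd1, Sox2, Pax6, Eomes and Tubb3. The text takes a selection of them; Eomes was not tested, being below the minimum. Genes that share the name of an item withheld for evaluations were left out.

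The alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5 TPM, median-ratio scaling, quantile normalization, moderation without a trend, a minimum change of 1.5-fold, a block for the replicate number, only the compared groups in the fit, leaving out each library in turn, an estimated correlation and the fry test for lists, and shared libraries split between comparisons. Leaving out the 3 libraries numbered 3 together was added after seeing the data. The chance level of overlap between comparisons that share libraries was taken from 20 simulated data sets with no group effect and independent noise. In each, as many genes as were called in the real data were taken by p rank, without a threshold. The method was tested on simulated data with 200 of 15216 genes changed in each comparison: at log2 changes of 0.5, 1, 2 and 3 it recovered 14%, 50%, 94% and 100% for Upf2 Cre against mock, 6%, 58%, 94% and 98% for Upf2 Trp53 Cre against mock, and 16%, 62%, 94% and 100% between the Cre groups. Of the unchanged genes, 8, 5 and 8 were called. The simulated noise was independent between libraries and had no structure by replicate number, so these rates need not hold for the real libraries. Parent genes of pseudogenes were found with BLAST 2.17.0, and plots were drawn with Matplotlib 3.10.9 under Python 3.11.15. Trp53-only knockout cells, which the series text also mentions, are not among the samples and are not analysed here.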

Results

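Total RNA was sequenced from 18 cultures of mouse C57BL/6 cortical neural progenitor cells, the dividing cells that give rise to the neurons and glia of the cortex. The labels divide them into 3 groups of 6 libraries, each with replicates 3, 4, 5, 6, 8 and 9. The Upf2 mock libraries came from cells with floxed Upf2 alleles given medium only. The Upf2 Cre libraries came from the same line given an adeno-associated virus carrying Cre recombinase. The Upf2 Trp53 Cre libraries came from cells with floxed alleles of both genes given the same virus. Upf2 encodes a core factor of nonsense-mediated mRNA decay (NMD), the pathway that degrades transcripts with premature stop codons, and Trp53 encodes the transcription factor p53. The series title poses the question of how NMD and TRP53 interact in progenitor maintenance and brain size. A mock group of the doubly floxed line is not among the samples, so the Trp53 genotype goes with the line. No library had a virus without Cre, so virus exposure goes with Cre. The deposited unit, TPM (transcript abundance scaled to a fixed total per library), keeps no read total, so the depth of each library is unknown. Between 14019 and 15210 genes per library had at least 1 TPM, and 15216 genes entered the tests.

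The levels of the targeted genes are given first. Upf2 (ENSMUSG00000043241.14; mm10 chromosome 2, 5951469 to 6056703, plus strand) averaged 11.1 ± 2.98 TPM (SD, n = 6) in mock, 20.2 ± 4.82 in the Upf2 Cre libraries and 33.8 ± 9.03 in the Upf2 Trp53 Cre libraries. Its log2 difference was 0.82 for Upf2 Cre against mock (exact permutation p = 0.0043, adjusted p = 0.0065) and 1.52 for Upf2 Trp53 Cre against mock (exact permutation p = 0.0022, adjusted p = 0.0043). Between the Cre groups it was 0.70 higher in the Upf2 Trp53 Cre libraries (exact permutation p = 0.013, adjusted p = 0.016). These differences run against what the labels would give for a lost transcript. A gene-level TPM also counts exons outside a floxed segment, so it does not measure the deletion, and the groups are named here as labelled. Trp53 (ENSMUSG00000059552.13; chromosome 11, 69580359 to 69591873, plus strand) averaged 104 ± 18.2 TPM in mock, 138 ± 35.0 in Upf2 Cre and 16.5 ± 1.69 in Upf2 Trp53 Cre (SD, n = 6). It fell by 2.57 on the log2 scale in Upf2 Trp53 Cre against mock and fell by 2.96 against Upf2 Cre, each with an exact permutation p = 0.0022, the smallest that 6 against 6 libraries allow. For Trp53 in Upf2 Cre against mock the log2 difference of 0.39 did not pass the test (exact permutation p = 0.071); without the libraries numbered 3 it was 0.45 and passed by limma (adjusted p = 0.010).

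**Figure D1:**
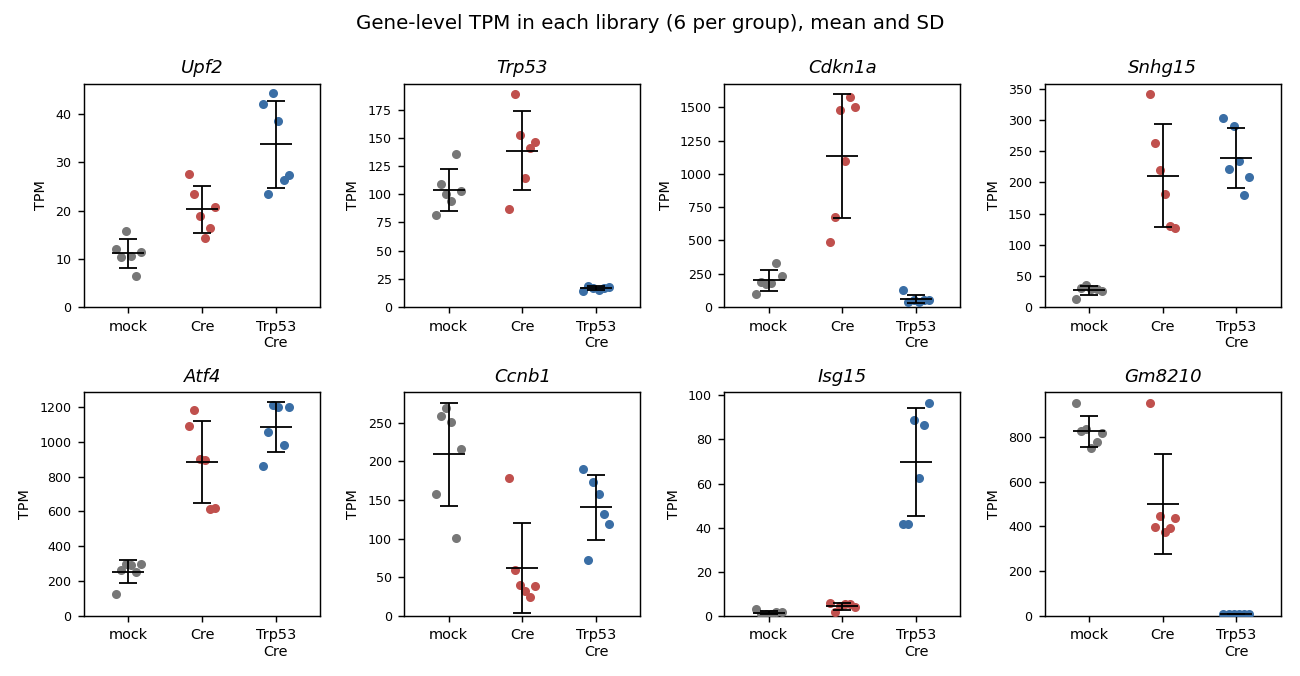
TPM of 8 genes on linear axes in each of the 18 libraries, by labelled group. Points are libraries, and the line and bar give the mean and SD of 6 libraries. Trp53 averaged 16.5 TPM in the Upf2 Trp53 Cre libraries against 104 in mock, and Isg15 averaged 69.7 against 1.45.

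Upf2 Cre against Upf2 mock asks what changed in floxed progenitors given the virus. Genes known as targets of p53 were higher in the Upf2 Cre libraries: 29 of 42 tested rose and 1 fell, the same counts when adjusted over the list alone. The list's median log2 difference was 1.13, which is 1.26 above the median of all tested genes (camera adjusted p = 1.3e-13; adjusted p = 0.070 with an estimated correlation). Cdkn1a (ENSMUSG00000023067.14; chromosome 17, 29090976 to 29100727), which encodes the p21 inhibitor of cyclin-dependent kinases, averaged 1135 ± 464 TPM against 201 ± 77.9 in mock (SD, n = 6; log2 difference 2.46 ± 0.33 SE, adjusted p = 7.4e-05). The cell death genes Bbc3, which encodes PUMA, and Tnfrsf10b, which encodes a death receptor, rose by log2 2.13 and 2.45, and Bax rose by 1.51. Pidd1 and Sesn2 rose by 2.14 and 2.28, and Mdm2, whose product degrades p53, rose by 0.73. Ccng1 and Eda2r, also p53 targets, did not pass the test, with log2 differences of 0.64 and 0.10 (adjusted p = 0.14 and 0.76). Of 28 tested apoptosis genes, 11 rose and 4 fell, or 12 and 5 adjusted over the list alone (median 0.25, camera adjusted p = 0.0044; adjusted p = 0.098 with an estimated correlation). Of the 29 apoptosis genes fixed beforehand, 6 are also on the p53 target list.

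Of 28 tested transcripts described as NMD targets, 14 rose, 4 fell and 10 did not pass the test in the Upf2 Cre libraries, with 17 up and 5 down adjusted over the list alone (median 0.85, camera adjusted p = 1.9e-06; adjusted p = 0.15 with an estimated correlation). Gadd45b, a stress gene whose transcript NMD degrades, rose from 3.81 ± 1.45 to 24.1 ± 8.46 TPM (SD, n = 6; log2 difference 2.38). Atf4 (ENSMUSG00000042406.8; chromosome 15, 80255184 to 80257541), which encodes the transcription factor of the integrated stress response, rose from 254 ± 66.2 to 883 ± 235 TPM (log2 difference 1.81). Of 17 tested small nucleolar RNA host genes, 7 rose and 1 fell, in both adjustments (median 0.42, camera adjusted p = 1.8e-04; adjusted p = 0.16 with an estimated correlation). Snhg15 (ENSMUSG00000085156.7; chromosome 11, 6525591 to 6528760) rose from 26.9 ± 7.49 to 211 ± 82.8 TPM (log2 difference 2.89), and Zfas1 rose by 3.12. Gas5, another host gene, did not pass the test (log2 difference 0.42, adjusted p = 0.27). Of 9 tested NMD factors other than Upf2, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.69, camera adjusted p = 0.0026; adjusted p = 0.26 with an estimated correlation). Smg5 and Smg9 rose by 1.25 and 1.22, while Smg1 and Upf3b did not pass the test, with 0.26 and 0.40; Upf3b passed it under both other scalings, with 0.56 and 0.49. Of the 28 described NMD targets, 20 are also on another of the lists.

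Genes of the integrated stress response rose as well: 13 of 24 rose and 2 fell, in both adjustments (median 0.91, camera adjusted p = 1.6e-04; adjusted p = 0.38 with an estimated correlation). Ddit3, which encodes CHOP, rose by 2.32 and Ppp1r15a, which encodes the phosphatase subunit GADD34, rose by 1.91. Of 18 tested genes of the unfolded protein response 0 rose and 7 fell, in both adjustments (median -0.44), and the list did not pass the test (camera adjusted p = 0.092). It passed without the libraries numbered 3 (adjusted p = 0.046), with 11 falls, and 4 of its genes fell under median-ratio scaling. Of 13 tested interferon response genes 4 rose and 0 fell, in both adjustments, with a list median of 0.22 (camera adjusted p = 0.046; adjusted p = 0.66 with an estimated correlation). Without the libraries numbered 3 that list no longer passed the test (adjusted p = 0.078), nor did it with no minimum on low values (adjusted p = 0.053).

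Cell cycle genes were lower in the Upf2 Cre libraries. Of 29 tested genes of G2 and M phase, 24 fell and 0 rose, or 26 and 0 adjusted over the list alone (median -1.03, camera adjusted p = 3.7e-08; adjusted p = 0.40 with an estimated correlation). Ccnb1 (ENSMUSG00000041431.16; chromosome 13, 100778650 to 100786570), which encodes cyclin B1, fell from 209 ± 66.8 to 61.9 ± 58.2 TPM (SD, n = 6; log2 difference -2.02, adjusted p = 8.7e-04). Tpx2, Prc1 and Aurka, which encode spindle and cell division proteins, had log2 differences of -1.59, -1.28 and -1.25. Of 30 tested genes of G1/S and DNA replication, 14 fell and 0 rose, in both adjustments (median -0.73, camera adjusted p = 0.0045; adjusted p = 0.66 with an estimated correlation), among them Rrm1, which encodes a ribonucleotide reductase subunit and fell by 1.73. Without the libraries numbered 3, 27 of these 30 fell. Of 23 tested primary microcephaly genes 1 rose and 12 fell, in both adjustments (median -0.50), and the list missed the threshold (camera adjusted p = 0.061). It passed narrowly under median-ratio scaling (camera adjusted p = 0.0499). Aspm, a spindle pole gene on it, fell by 1.11. Of 25 splicing factor genes of the SR and related families 9 fell and 0 rose, in both adjustments (median -0.52, camera adjusted p = 0.018; adjusted p = 0.66 with an estimated correlation), with Srsf7 at -1.54 and Hnrnpa1 at -1.24. The cyclin gene Ccnd1, at 1442 ± 410 TPM against 713 ± 351, missed the threshold (adjusted p = 0.055); it passed without the libraries numbered 3 (log2 difference 0.89, adjusted p = 7.5e-05) and under both other scalings. Upf2 Cre replicate 3 stood apart in this group: its Ccnb1 level was 178 TPM, within the mock range of 101 to 269, while the other Upf2 Cre libraries held 24.1 to 58.9.

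Among cell type markers, 7 of 16 radial glia genes fell and 0 rose, in both adjustments, without a call for the list (median -0.43, camera adjusted p = 0.19); under median-ratio scaling 3 fell, under quantile normalization 4 fell, and without the libraries numbered 3 there were 4 rises beside 7 falls. Slc1a3, a glutamate transporter gene of radial glia and astrocytes, fell by 1.54, and Fabp7 fell by 1.46. Of 10 astrocyte genes 1 rose and 5 fell, in both adjustments (median -0.82, camera adjusted p = 0.22), with Gja1 at -1.62. Of 12 neuron genes 3 rose and 1 fell, or 1 and 1 adjusted over the list alone (median 0.33, camera adjusted p = 0.18). The neuronal tubulin gene Tubb3 missed the threshold (log2 difference 0.91, adjusted p = 0.052; 0.035 under median-ratio scaling). Of 6 intermediate progenitor genes 2 rose and 0 fell, and of 7 oligodendrocyte lineage genes 1 rose and 1 fell, in both adjustments, neither list passing the test (camera adjusted p = 0.20 and 0.93). Of 13 mitochondrially encoded mRNAs 1 rose and 0 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.13); without the libraries numbered 3, 7 rose and the list passed the test (adjusted p = 0.041). Microglial, vascular and interneuron markers had too few tested members; their summed TPM in mock and Upf2 Cre averaged 0.157 and 0.256, 1.30 and 1.76, and 2.45 and 2.03. The vascular sum differed between these groups (exact permutation p = 0.0043, adjusted p = 0.013).

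In all, 2506 genes rose and 3686 fell in Upf2 Cre against mock (limma, adjusted p under 0.05), 40.5% of the changed genes upward. Among changed genes whose groups did not overlap, the largest rises included Col18a1 (log2 difference 3.50), which encodes a basement membrane collagen, Gadd45g (3.44) and Dcxr (3.18). The largest falls included the glutamate receptor gene Grm3 (-2.25), the adhesion molecule gene Vcam1 (-2.24) and Vit (-2.19). In 892 genes, 5.86% of those tested, the groups did not overlap, against 0.216% by chance. The median log2 difference of all tested genes was -0.12, and the upward share was 53.1% with libraries rescaled by median ratios (3309 up, 2928 down) and 48.2% with quantile normalization (2982 up, 3210 down). Without the 3 libraries numbered 3, 3885 genes rose and 5070 fell.

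Upf2 Trp53 Cre against Upf2 mock asks what changed where both genes were floxed, against the mock of the singly floxed line. Of 22 gene names on the interferon response list 13 were tested. Of these 12 rose and 0 fell, or 13 and 0 adjusted over the list alone (median 1.62, camera adjusted p = 1.2e-18, and 0.021 with an estimated correlation). Of the other 9, 8 missed the minimum of 1 TPM in 6 libraries, which a gene high in 1 group alone can meet. The name Rigi was absent from the table, but it is another name of Ddx58, which was tested. With that minimum applied to the mock and Upf2 Cre libraries alone, 9 of 10 rose and 0 fell (median 1.48, camera adjusted p = 3.9e-14), and with no minimum 20 of 21 rose and 0 fell (median 1.39). Isg15 (ENSMUSG00000035692.7; chromosome 4, 156199424 to 156200818), an interferon-induced ubiquitin-like modifier, averaged 69.7 ± 24.5 TPM against 1.45 ± 0.846 in mock (SD, n = 6; log2 difference 4.84 ± 0.28 SE, adjusted p = 2.6e-10). Cxcl10, a chemokine gene, rose by 4.62, Rsad2, which encodes viperin, by 2.67, and Oasl1 by 4.06. The summed TPM of 10 microglial marker genes averaged 0.374 ± 0.158 in these libraries and 0.157 ± 0.147 in mock (SD, n = 6; exact permutation p = 0.032, adjusted p = 0.065).

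Described NMD targets rose in 18 of 28 and fell in 0, or 20 and 0 adjusted over the list alone (median 1.26, camera adjusted p = 1.3e-13; adjusted p = 0.045 with an estimated correlation). Gadd45b reached 47.3 ± 11.5 TPM and Atf4 1085 ± 144 (SD, n = 6), log2 differences of 3.35 and 2.14. Small nucleolar RNA host genes rose in 9 of 17 and fell in 0, or 11 and 0 adjusted over the list alone (median 1.24, camera adjusted p = 1.3e-07; adjusted p = 0.070 with an estimated correlation), with Snhg15 up by 3.14, Zfas1 by 3.61 and Gas5 by 1.29. NMD factors rose in 6 of 9 and fell in 0, or 7 and 0 adjusted over the list alone (median 0.92, camera adjusted p = 1.1e-05; adjusted p = 0.082 with an estimated correlation), with Smg5 up by 1.38, Smg1 by 1.04 and Smg9 by 0.94. Genes of the integrated stress response rose in 15 of 24 and fell in 0, or 17 and 0 adjusted over the list alone (median 1.19, camera adjusted p = 1.3e-11; adjusted p = 0.071 with an estimated correlation). Atf3 rose by 3.61, Ddit3 by 2.98 and Ppp1r15a by 2.14. Of 18 unfolded protein response genes 3 rose and 0 fell, in both adjustments, and the list did not pass the test (median 0.03, camera adjusted p = 0.62).

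The p53 target genes were lower here: 3 of 42 rose and 12 fell, or 5 and 14 adjusted over the list alone (median -0.35, camera adjusted p = 1.0e-08; adjusted p = 0.15 with an estimated correlation). Eda2r, a receptor gene of the tumour necrosis factor family, fell from 21.1 ± 6.61 to 0.997 ± 0.715 TPM (SD, n = 6; log2 difference -3.48), and Ccng1 fell by 2.94. Cdkn1a fell to 60.4 ± 33.6 TPM, a log2 difference of -1.76, while Bbc3, Bax and Mdm2 did not pass the test, with -0.34, -0.25 and -0.15. Apoptosis genes rose in 4 of 28 and fell in 1, or 7 and 1 adjusted over the list alone, without a call for the list (median 0.13, camera adjusted p = 0.81).

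Of the 29 genes of G2 and M phase, 0 rose and 0 fell by limma, in both adjustments (median -0.12, camera adjusted p = 0.069; 0.0052 without the libraries numbered 3); Prc1 averaged 56.2 ± 11.8 TPM against 57.5 ± 16.6 in mock. Of 30 genes of G1/S and DNA replication 0 rose and 0 fell, in both adjustments (median 0.07, camera adjusted p = 0.25); without the libraries numbered 3, 5 fell and the list passed the test (median -0.30, adjusted p = 5.9e-04). Over all tested genes, 3719 had an unadjusted p under 0.05. Of 23 microcephaly genes 2 rose and 0 fell, or 4 and 0 adjusted over the list alone (median 0.17, camera adjusted p = 0.36). Of 25 splicing factor genes 2 rose and 0 fell, in both adjustments (median -0.07, camera adjusted p = 0.18). Among cell type markers, neuron genes rose in 4 of 12 and fell in 0, or 5 and 0 adjusted over the list alone (median 0.46, camera adjusted p = 0.18), with the neurofilament gene Nefm up by 1.57. The astrocyte list was lower with 1 of 10 genes fallen and 0 risen, or 3 and 0 adjusted over the list alone (median -0.48, camera adjusted p = 0.0081; adjusted p = 0.49 with an estimated correlation, and 0.099 without the libraries numbered 3); the fallen gene was Gja1 (-1.28). The radial glia list had 1 of 16 fallen, or 0 adjusted over the list alone (median -0.08, camera adjusted p = 0.048; adjusted p = 0.43 with an estimated correlation). That call was lost under median-ratio scaling (adjusted p = 0.057), with a pseudocount of 0.1 (0.051) and without the libraries numbered 3 (0.12). Of 6 intermediate progenitor genes 1 rose, and of 7 oligodendrocyte lineage genes and 13 mitochondrially encoded mRNAs 0 changed, in both adjustments (camera adjusted p = 0.60, 0.22 and 0.40). The summed vascular markers averaged 4.22 ± 0.962 TPM and the summed interneuron markers 8.73 ± 2.47 (SD, n = 6), above mock with exact permutation p = 0.0022 and 0.0065 (adjusted p = 0.0087 and 0.016).

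In all, 1586 genes rose and 166 fell in Upf2 Trp53 Cre against mock (limma, adjusted p under 0.05), 90.5% of the changed genes upward. The largest rise was in Rab3b (ENSMUSG00000003411.10; chromosome 4, 108879063 to 108943324), which encodes a vesicle trafficking GTPase and went from 3.46 ± 0.918 to 216 ± 33.0 TPM (SD, n = 6; log2 difference 5.61). Mir7688 was listed at 0 in the mock and Upf2 Cre libraries and averaged 23.6 ± 10.8 TPM here. The largest falls were in Gm8210 (ENSMUSG00000094497.1; chromosome 1, 43189156 to 43189638), a processed pseudogene that went from 827 ± 69.3 to 8.11 ± 1.24 TPM, and Tma7-ps (-5.62). Gm8210 matches the ribosomal protein gene Rpl29, which rose by 2.29, at 99.4% of bases. In 1205 genes, 7.92% of those tested, the groups did not overlap, against 0.216% by chance. The upward share was 75.0% under median-ratio scaling (1114 up, 372 down) and 69.3% under quantile normalization (1081 up, 478 down). The count of falls was 373 without Upf2 mock replicate 8 and 274 without Upf2 Cre replicate 3, and without the 3 libraries numbered 3 it was 680, with 2874 rises.

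Upf2 Trp53 Cre against Upf2 Cre asks how the doubly floxed cells differed from the singly floxed cells when both had been given the virus. The p53 target genes were lower in the doubly floxed cells: 29 of 42 fell and 0 rose, or 33 and 0 adjusted over the list alone. The list's median log2 difference was -1.72, which is -1.97 relative to the median of all tested genes (camera adjusted p = 1.0e-48; adjusted p = 0.0020 with an estimated correlation). Cdkn1a fell by 4.22 ± 0.33 SE on the log2 scale (adjusted p = 3.7e-08), from 1135 ± 464 to 60.4 ± 33.6 TPM (SD, n = 6). Dglucy (-3.77), Ak1 (-3.76), Eda2r (-3.59), Ccng1 (-3.58) and Psrc1 (-2.02) fell too, as did the cell death genes Tnfrsf10b (-2.91), Bbc3 (-2.47) and Bax (-1.76). Mdm2 fell by 0.89. Apoptosis genes rose in 3 of 28 and fell in 8, or 4 and 8 adjusted over the list alone (camera adjusted p = 9.7e-04, lower; adjusted p = 0.070 with an estimated correlation). For that list the median was 0.11 while the mean and the test were negative (mean -0.29); under median-ratio scaling the median was -0.15.

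Cell division genes were higher in the doubly floxed cells. Of 29 genes of G2 and M phase, 20 rose and 0 fell, or 26 and 0 adjusted over the list alone (median 1.02, which is 0.77 above the median of all tested genes; camera adjusted p = 1.0e-08; adjusted p = 0.38 with an estimated correlation). Aurka rose from 71.4 ± 50.05 to 171 ± 23.3 TPM (SD, n = 6; log2 difference 1.49), Prc1 by 1.27 and Tpx2 by 1.26. Under median-ratio scaling 13 of the 29 rose. Upf2 Cre replicate 3 again stood apart from its group, with Ccnb1 at 178 TPM against 24.1 to 58.9 in the other 5. Of 30 genes of G1/S and DNA replication 3 rose and 0 fell, or 10 and 0 adjusted over the list alone (median 0.74, camera adjusted p = 0.0064; adjusted p = 0.66 with an estimated correlation); 23 rose without the libraries numbered 3, and 1 rose under median-ratio scaling. Microcephaly genes rose in 12 of 23 and fell in 0, or 14 and 0 adjusted over the list alone (median 0.61, camera adjusted p = 3.7e-04; adjusted p = 0.49 with an estimated correlation), with Aspm up by 1.04; 3 rose under each of the other scalings. Splicing factor genes rose in 1 of 25 in both adjustments (median 0.44, camera adjusted p = 0.038; adjusted p = 0.66 with an estimated correlation), and in 9 without the libraries numbered 3.

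Of 13 tested interferon response genes 12 rose and 0 fell, in both adjustments (median 1.45, camera adjusted p = 3.0e-13; adjusted p = 0.045 with an estimated correlation), with Isg15 up by 3.71 and Cxcl10 by 3.29. With the minimum applied to the mock and Upf2 Cre libraries alone 9 of 10 rose (median 1.03). Microglial markers summed to 0.374 TPM here and 0.256 in Upf2 Cre, a difference that did not pass the exact permutation test (p = 0.19). Described NMD targets rose in 4 of 28 and fell in 0, or 5 and 0 adjusted over the list alone (median 0.48, camera adjusted p = 0.027; adjusted p = 0.64 with an estimated correlation); 18 rose without the libraries numbered 3, 2 under quantile normalization and 0 under median-ratio scaling. Atf4, Snhg15 and Smg5 did not pass the test, with log2 differences of 0.33, 0.25 and 0.13, of which those of Snhg15 and Smg5 turned to -0.02 and -0.14 under median-ratio scaling; Atf4 passed without the libraries numbered 3 (0.46). Host genes of small nucleolar RNAs rose in 1 of 17, or 0 adjusted over the list alone, and NMD factors in 2 of 9 in both adjustments, neither list passing the test (camera adjusted p = 0.37 and 0.77). Without the libraries numbered 3, 6 host genes rose. Under median-ratio scaling and under quantile normalization 0 host genes and 0 NMD factors rose. Integrated stress response genes rose in 10 of 24 and fell in 2, in both adjustments (median 0.67, camera adjusted p = 0.048; adjusted p = 0.66 with an estimated correlation). Atf3 rose by 1.61 and Slc7a11, which encodes a cystine transporter, by 1.72, while Sesn2 fell by 1.32. That list's call was lost with a pseudocount of 0.1 (adjusted p = 0.051), and 3 of its genes rose under median-ratio scaling and 5 under quantile normalization. The unfolded protein response list, with 3 of 18 risen, or 8 adjusted over the list alone (median 0.40, camera adjusted p = 0.048; adjusted p = 0.66 with an estimated correlation), lost its call with the same pseudocount (0.051) and under median-ratio scaling (0.15).

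Among cell type markers, 1 of 16 radial glia genes rose, 2 of 12 neuron genes rose with Nefm up by 1.06, and 1 of 6 intermediate progenitor genes fell, in both adjustments (camera adjusted p = 0.97, 0.82 and 0.22). By limma 0 of 10 astrocyte and 0 of 7 oligodendrocyte lineage genes changed (camera adjusted p = 0.43 and 0.18), among 5262 genes of all those tested with an unadjusted p under 0.05. Mitochondrially encoded mRNAs changed in 0 of 13 and were lower as a list (median -0.27, camera adjusted p = 0.0016; adjusted p = 0.38 with an estimated correlation). They made up 5.84 ± 0.42% of the TPM in Upf2 Trp53 Cre, 7.16 ± 1.57% in Upf2 Cre and 6.22 ± 0.90% in mock (SD, n = 6). The difference in this share between the Cre groups did not pass the exact permutation test (p = 0.082, adjusted p = 0.14). The summed interneuron markers were higher in the doubly floxed cells, 8.73 against 2.03 TPM, as were the vascular markers, 4.22 against 1.76 (each exact permutation p = 0.0022, adjusted p = 0.0087).

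In all, 1791 genes rose and 374 fell between the Cre groups (limma, adjusted p under 0.05), 82.7% of the changed genes upward. Besides Rab3b (log2 difference 4.95), the largest rises included the pseudogene Gm6344 (3.80), the noncoding transcripts AA465934 (3.16) and Six3os1 (3.12) and the ribosomal protein gene Rpl29 (2.94). The largest falls included Gm8210 (-5.71), the vesicle protein gene Svop (-5.55) and Dcxr (-5.16). In 414 genes, 2.72% of those tested, the groups did not overlap, against 0.216% by chance. The median log2 difference of all tested genes was 0.25, and the upward share was 36.4% under median-ratio scaling (353 up, 618 down) and 47.7% under quantile normalization (539 up, 592 down). Leaving out 1 library moved the count of rises by more than 1.5 times in 11 cases: to 4139 without Upf2 Cre replicate 3 and 2935 without Upf2 Trp53 Cre replicate 4. The others were 705, 687, 427 and 642 without Upf2 Cre replicate 5, 6, 8 or 9, and 1018, 556, 686, 1024 and 983 without Upf2 Trp53 Cre replicate 3, 5, 6, 8 or 9. The count of falls was 1375 without Upf2 Cre replicate 3; it was 188, 243, 171 and 181 without Upf2 Cre replicate 5, 6, 8 or 9 and 240, 198, 203 and 243 without Upf2 Trp53 Cre replicate 3, 5, 6 or 8. Without the 3 libraries numbered 3, 4264 genes rose and 1326 fell.

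Of the genes changed in Upf2 Cre against mock, 1364 changed in the opposite direction between Upf2 Trp53 Cre and Upf2 Cre and 79 in the same direction. Among the 2506 that had risen, 302 were lower in the doubly floxed cells, Cdkn1a and Bax among them, 67 were higher and 2137 were not called, Atf4 and Snhg15 among these. Among the 3686 that had fallen, 1062 were higher in the doubly floxed cells, Aurka and Prc1 among them, 12 were lower and 2612 were not called. Both comparisons use the Upf2 Cre libraries. Simulated data with that sharing, no group effect and independent noise gave 1235 opposite and 66.9 in the same direction. There the same numbers of genes were taken by p rank without a threshold, so these counts are not matched to called genes. The noise had no structure by replicate number, and with a block for that number 2976 real genes were opposite and 174 the same. The correlation of log2 differences across genes, which are not independent replicates, was -0.69 against -0.50 in the simulations, and the covariance was -0.24 against -0.04. With the Upf2 Cre libraries split between the comparisons, 495 and 114 genes were opposite and 32 and 15 the same. Leaving out 1 library moved the count of opposite genes to 4299 without Upf2 Cre replicate 3 and 2260 without Upf2 Trp53 Cre replicate 4. It was 497, 560, 333 and 495 without Upf2 Cre replicate 5, 6, 8 or 9, and 756, 474, 567, 763 and 804 without Upf2 Trp53 Cre replicate 3, 5, 6, 8 or 9. The count in the same direction was 123 without mock replicate 3, 42, 37, 29 and 36 without Upf2 Cre replicate 5, 6, 8 or 9, and 36, 46 and 49 without Upf2 Trp53 Cre replicate 5, 6 or 9. Under median-ratio scaling 697 were opposite and 38 the same, and without the 3 libraries numbered 3 these counts were 4254 and 173.

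Against mock, 1142 genes changed with the same sign in both Cre groups, 1031 up and 111 down, and 20 with opposite signs. Snhg15, Zfas1, Gadd45b, Atf4, Ddit3 and Smg5 rose in both, and Gja1 fell in both. The mock libraries are shared, and the same simulated data, with genes again taken by p rank without a threshold, gave 1024 with the same sign and 53.3 opposite. The correlation across genes was 0.67 against 0.50 in the simulations, and the covariance was 0.23 against 0.04. With the mock libraries split between the comparisons, 470 and 399 genes had the same sign, and without the 3 libraries numbered 3 the count was 2638.

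**Figure D2:**
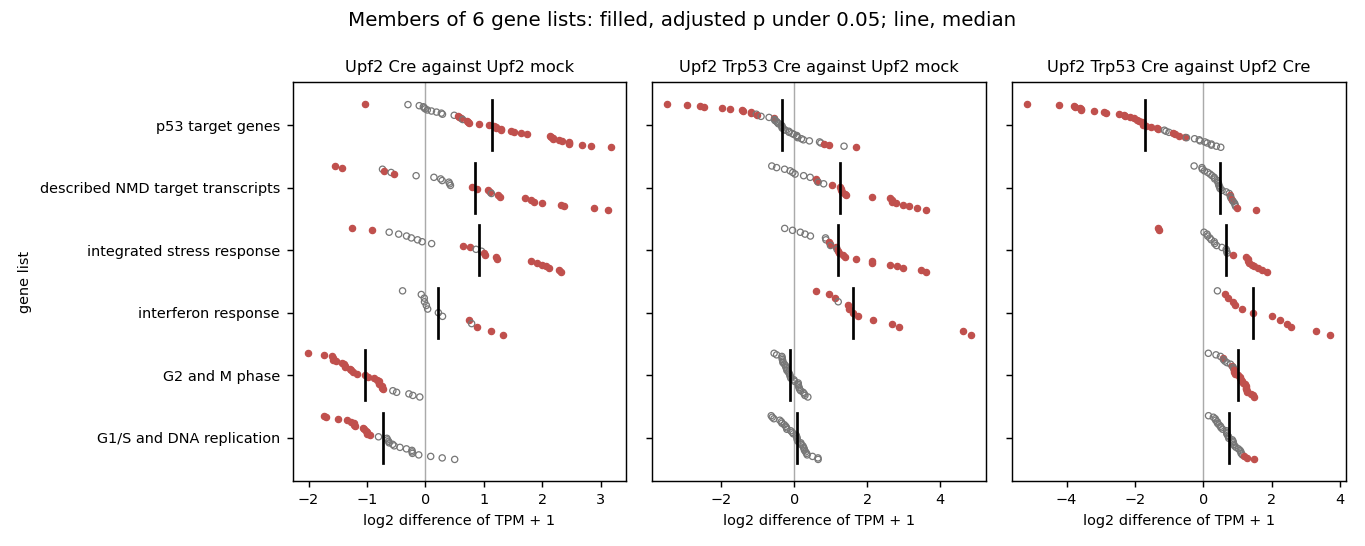
Log2 difference of each tested member of 6 gene lists in the 3 comparisons; each point is a gene, filled where its adjusted p is under 0.05, and the line is the list's median. The median of the p53 target genes was 1.13 in Upf2 Cre against mock, -0.35 in Upf2 Trp53 Cre against mock and -1.72 between the Cre groups.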

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

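The tests of outlying libraries, of reads shared with parent genes, of exchanged labels and of feedback on NMD factors were chosen after the results were seen, as were the exchanges of single libraries and the counts without the libraries numbered 3.

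Of 13 tested interferon response genes 12 rose in the Upf2 Trp53 Cre libraries against each other group, with medians of 1.62 against mock and 1.45 against Upf2 Cre, or 1.48 and 1.03 over the 10 members that pass the minimum in the other 2 groups alone. Microglia as a sizeable part of the cultures are argued against by the summed TPM of 10 microglial markers. It averaged 0.374 in the Upf2 Trp53 Cre libraries, with Csf1r the highest at 0.277, against 0.256 in Upf2 Cre and 0.157 in mock. Markers of other immune cells were not summed, so other immune cells were not tested. A few outlying libraries are argued against for the 8 of 13 genes that had every Upf2 Trp53 Cre library above every Upf2 Cre library, and 9 had all above every mock library. Ifit3 and Oasl2 are among these genes but met the minimum only with the Upf2 Trp53 Cre libraries counted, which favours such a separation. A shift in cell make-up stays open, since summed vascular markers (4.22 TPM against 1.76 in Upf2 Cre and 1.30 in mock) and interneuron markers (8.73 against 2.03 and 2.45) were higher in the same libraries. Much of the interneuron sum there came from 1 gene, Dlx2, at 4.45 TPM. Also open are the Trp53 genotype, a difference between the lines, which goes with it and has no mock group to measure it, and a response to the virus that depends on either.

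In 25 genes the Upf2 Trp53 Cre libraries differed at least 4-fold from both other groups, which differed less than 2-fold, 17 of them higher and 8 lower; Rab3b, Gm8210, Mir7688 and Rpl29 are among them. A chromosome segment carried along with the Trp53 locus is argued against as the site of all 25 genes, since 5 lay on chromosome 11 (upper 95% exact bound 40.7%). That was 20% against 7.81% of tested genes (one-sided Fisher's exact p = 0.041). The 5 include the targeted gene Trp53 itself, on which that p in part rests, and the p53 target Ccng1. Within 10 Mb of Trp53 lay 2, Trp53 and Xaf1, the latter chosen after its values were seen. AA465934, also on chromosome 11, lay farther away. Effects of such a segment on genes elsewhere were not tested. Reads shared between a copy and its parent gene could explain part. Of 6 pseudogenes 2, Gm8210 and Mid1-ps1, had a parent called in the opposite direction (95% exact bounds 4.33% to 77.7%). The bounds take the pseudogenes as independent, though Gm8210, Gm6344 and Gm10709 have the same parent, Rpl29. Gm10709 matches it at 99.2% of bases and rose by 2.29 against mock, as Rpl29 did. Mid1-ps1 and Gm10709 were also chosen after their values were seen. Gm8210 and Gm6344 match Rpl29 at 99.4% of bases; Gm8210 fell by 6.51 against mock while Gm6344 and Rpl29 rose by 3.38 and 2.29, so a sequence variant between the lines and a change in expression cannot be told apart without reads. A difference between the lines elsewhere in the genome and an effect of Trp53 loss, with known p53 targets such as Eda2r among the 25, stay open and untested.

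Some values ran against the Cre labels. Upf2 TPM was higher in both Cre groups. Upf2 Cre replicate 3 lay nearer to the mock mean (0.88, root mean square log2 distance over 1000 genes that vary most between group means) than to its own group's (1.71). It was the 1 library of 18 nearest to another group. The genes and means came from the libraries not numbered 3, which favours those libraries. Mock replicate 3 (0.98) and Upf2 Trp53 Cre replicate 3 (0.82) were still nearest to their own groups. Exchanged Cre and mock labels are argued against by the described NMD targets, whose median was 0.85 higher in Upf2 Cre (camera adjusted p = 1.9e-06, but 0.15 with an estimated correlation). For Upf2 TPM, feedback on NMD factor transcripts is a candidate explanation, since the other factors were higher by a median of 0.69 in Upf2 Cre and 0.92 in Upf2 Trp53 Cre (adjusted p = 0.26 and 0.082 with an estimated correlation). An exchange of Upf2 Cre replicate 3 with a mock library is argued against because it lay above all mock libraries in 14 of the 18 described NMD targets that rose without the libraries numbered 3 (lower 95% exact bound 52.4%, which takes the genes as independent though they are not), with Snhg15 at 342 TPM and Atf4 at 1090 against at most 35.0 and 296 in mock; of the possible partners, mock replicate 3 lay below the other Upf2 Cre libraries in 13 of the 18 and mock replicate 8 in 17. Against the other Upf2 Cre libraries it was lowest in Cdkn1a (489 TPM against 674 to 1575) and highest in Snhg15 (342 against 127 to 263), Gadd45b (39.9 against 15.9 to 25.5), Gas5 (323 against 80.9 to 147) and Ddit3 (106 against 29.4 to 37.8), and what sets it apart stays open and untested.

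Random splits of each pair of groups into 6 and 6 libraries were drawn, 100 counted with the real one, out of 462 possible. In each comparison the share with at least the real count was under 0.05. The splits treat the libraries as exchangeable, and exchanging 1 library could raise the count above the real one, so chance is not excluded. For Upf2 Cre against mock 2 splits gave at least the real 6192 genes, the highest other 6506, and it exchanges Upf2 Cre replicate 3 with mock replicate 3. For Upf2 Trp53 Cre against mock 1 split, the real one, gave 1752 genes, and the highest other gave 245. Between the Cre groups 2 splits gave at least 2165 genes, and the highest other, 7097, several times the real count, exchanges Upf2 Cre replicate 3 with Upf2 Trp53 Cre replicate 4, which points to a structure of the samples beyond the groups. Trp53 was at 86.6 TPM in Upf2 Cre replicate 3 and 18.4 in Upf2 Trp53 Cre replicate 4, each on the side of its label. Exchanging Upf2 Cre replicate 3 with mock replicate 3, 8 or 9 gave 6506, 8836 and 6779 genes, more than the real 6192. Exchanging it with Upf2 Trp53 Cre replicate 4, 6, 8 or 9 gave 7097, 2357, 4435 and 5049, more than the real 2165, so 3 and 4 of the 6 exchanges called more genes than the labels did. Exchanging Upf2 Trp53 Cre replicate 3 with mock replicate 8 gave 3181, the 1 of 6 above the real 1752.

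A library lay apart from the 5 others of its group in 28 of 213 groups of values tested, and 18 of the 28 were libraries numbered 3. About 5% would by chance if the values were independent. They come from the same 18 libraries, so that rate is no baseline for the count. In Upf2 mock replicate 3, Tnfrsf10b was 1.26 TPM (others 3.28 to 4.06), Snhg15 12.96 (25.7 to 35.0), Atf4 124 (254 to 296), Mki67 53.3 (124 to 189) and Ccnd1 30.4 (690 to 1007), all lower. In the same library Zfas1 was 275 TPM (60.7 to 81.0), Snhg12 88.1 (20.4 to 28.4) and Vit 75.5 (20.8 to 31.2), all higher. In Upf2 Cre replicate 3, Ddit3 was 106 TPM (29.4 to 37.8), Pax6 8.34 (2.91 to 4.41), Srsf7 156 (32.6 to 56.3), Gm8210 953 (377 to 448) and Rpl29 509 (200 to 267). In Upf2 Trp53 Cre replicate 3, Cdkn1a was 127 TPM (37.5 to 55.6) and Ddit3 147 (47.3 to 67.2), while Ccnd1 was 476 (1010 to 1355) and AA465934 144 (217 to 265). Among other libraries, Mki67 was 139 TPM in Upf2 Cre replicate 4 (46.6 to 68.7) and Isg15 1.59 there (3.94 to 5.80). Rrm1 was 32.4 TPM in Upf2 Trp53 Cre replicate 4 (62.2 to 91.2) and Cxcl10 65.4 in replicate 5 (23.4 to 30.9). In mock replicate 8, Tma7-ps was 462 TPM (775 to 1015) and Six3os1 0.113 (0.387 to 0.483), and in Upf2 Cre replicate 9 Six3, chosen after its values were seen, was 0.8289 (0.197 to 0.370). Small noncoding RNA genes took 2.62% of TPM in mock replicate 6 (0.597% to 0.988%) and 17.1% in Upf2 Cre replicate 6 (0.585% to 2.57%). Upf2 Trp53 Cre replicate 6, not flagged, was also the highest of its group, at 2.66%. The most abundant gene took 3.90% in mock replicate 3 (2.05% to 2.35%) and 14.1% in Upf2 Cre replicate 6 (2.14% to 2.39%). The p53 target genes differed between the Cre groups by a median of -1.72, a difference that camera tested directly (adjusted p = 1.0e-48).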

How the results depend on the processing

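Leaving out the libraries numbered 3 and the changed minimums for the interferon list were chosen after seeing the data; other settings were planned. The interferon list in Upf2 Cre against mock lost its call with no minimum (adjusted p = 0.053). Tested directions did not turn in any setting run for the called lists and for a set of called genes named in the text. The other called genes were not checked for this. The apoptosis list's median between the Cre groups changed sign (0.11, and -0.15 under median-ratio scaling), its test negative in both. Medians of lists that missed the test changed sign in some settings: that of G1/S in Upf2 Trp53 Cre against mock went from 0.07 to -0.04 under median-ratio scaling and -0.30 without the libraries numbered 3, where it passed (adjusted p = 5.9e-04). Under median-ratio scaling 353 genes rose and 618 fell between the Cre groups, 372 fell in Upf2 Trp53 Cre against mock, and 697 opposite and 38 same-direction genes overlapped; under quantile normalization these were 539, 592, 478, 793 and 44. Without the libraries numbered 3, 3885 genes rose in Upf2 Cre against mock, 2874 rose and 680 fell in Upf2 Trp53 Cre against mock, and 4264 rose and 1326 fell between the Cre groups; 4254 were opposite, 173 the same, and 2638 shared by both Cre groups. With shared libraries split, 495 or 114 were opposite, 32 or 15 the same, and 470 or 399 shared by both Cre groups, with fewer libraries in each comparison. With an estimated correlation 0, 2 and 2 lists passed, against 10, 8 and 11. With the fry test 9, 8 and 9 passed, with 8 calls lost and 5 gained over the 3 comparisons. In Upf2 Cre against mock the G1/S (fry adjusted p = 0.11), splicing factor (0.057) and interferon (0.088) lists lost their calls. There the unfolded protein response (0.028) and radial glia (0.013) lists gained one. The main fit pools the spread of all 3 groups. With only the compared groups in the fit, 2065 genes rose and 3030 fell in Upf2 Cre against mock. In that setting 1784 rose and 196 fell in Upf2 Trp53 Cre against mock, and 1386 and 311 between the Cre groups. Trp53 in Upf2 Cre against mock was 0.45 and passed by limma without the libraries numbered 3 (adjusted p = 0.010). Apart from the splits and the smaller sets, the cause was not tested.

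With a block for the replicate number, 2532 genes rose and 438 fell in Upf2 Trp53 Cre against mock, 3586 rose and 859 fell between the Cre groups, 2976 were opposite, 174 the same and 2033 shared by both Cre groups; Trp53 in Upf2 Cre against mock, 0.39, passed (adjusted p = 0.018). With it the unfolded protein response list between the Cre groups (adjusted p = 0.11) and the radial glia list in Upf2 Trp53 Cre against mock (0.053) lost their calls. The numbers did not pair the libraries throughout: correlations of pairs ran from -0.08 to 0.58, -0.17 to 0.53 and -0.02 to 0.74 in the 3 comparisons, with 4, 5 and 5 of 6 pairs over 0.1 and 2, 3 and 3 correlating best with their own number.

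Leaving out 1 library at a time gave 1916 to 3507 rises and 2552 to 4771 falls in Upf2 Cre against mock, 1221 to 1986 and 112 to 373 in Upf2 Trp53 Cre against mock, and 427 to 4139 and 171 to 1375 between the Cre groups. It gave 333 to 4299 opposite, 29 to 123 same-direction and 837 to 1534 shared by both Cre groups. The extremes between the Cre groups came without Upf2 Cre replicate 8 (427, 171) and Upf2 Cre replicate 3 (4139, 1375). Among named genes, 73 of the results with a library left out lost a call, 38 gained one and 3399 stayed on the same side of the threshold, called or not. Depth is unknown, so its limit cannot be stated.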

Other observations

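The genes and groups in this part were chosen after their values were seen, apart from the lists and the test of annotated decay isoforms. Some homeobox genes were looked up because their values stood out in the Upf2 Trp53 Cre libraries; no list or enrichment of such genes was tested. Six3, which encodes a homeobox factor of the anterior forebrain, averaged 9.69 ± 2.56 TPM there, 0.392 ± 0.222 in Upf2 Cre and 0.330 ± 0.164 in mock (SD, n = 6), a log2 difference of 2.92 between the Cre groups. Its antisense neighbour Six3os1 averaged 11.96 ± 2.70 TPM against 0.480 and 0.394. Otx2, another homeobox gene, averaged 4.84 ± 1.46 TPM against 0.193 and 0.419. Dlx2, a homeobox gene of ventral forebrain progenitors and interneurons, averaged 4.45 ± 1.92 TPM against 0.255 ± 0.165 and 0.650 ± 1.12. Gad1, which encodes an enzyme that makes the transmitter GABA, averaged 2.20 ± 0.901, 1.51 ± 0.420 and 1.23 ± 0.699 TPM in the same order. Between the Cre groups Dlx2 passed the limma test (log2 difference 2.05, adjusted p = 1.1e-04) and Gad1 did not (0.31, adjusted p = 0.28). The summed TPM of the 8 interneuron markers, a list fixed beforehand, was 8.73 against 2.03. That sum includes Dlx2 (4.45 against 0.255) and Gad1, so it is not separate support for them, and 2 of its 8 members met the minimum.

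Ribosomal protein genes, a group picked after its values were seen and not tested for enrichment, were counted. Of 76 tested, 2 rose and 53 fell in Upf2 Cre against mock (median -1.03), where 3686 of all 15216 tested genes fell; 2 rose and 2 fell in Upf2 Trp53 Cre against mock (median -0.32), and 19 rose and 0 fell between the Cre groups (median 0.64). Against mock 45 fell in Upf2 Cre under median-ratio scaling and 46 under quantile normalization; between the Cre groups 1 and 12 rose under these, and 49 without the libraries numbered 3. In Upf2 Trp53 Cre against mock 23 fell without the libraries numbered 3. Pseudogenes, likewise picked afterwards and not tested for enrichment, fell in 548 of 1575 cases and rose in 72 in Upf2 Cre against mock, 34.8% fallen against 24.9% of protein-coding genes.

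One hypothesis was that genes with an annotated transcript of the nonsense-mediated decay class may have higher gene-level TPM in the Cre groups. Among 9649 protein-coding genes with 3 or more annotated transcripts, 3370 have such a transcript. Their median log2 difference against mock exceeded that of the others by 0.0156 in Upf2 Cre (camera adjusted p = 0.70) and 0.0597 in Upf2 Trp53 Cre (camera adjusted p = 0.21), so the test did not bear the hypothesis out. Gene-level TPM sum all transcripts of a gene, and a change in a minor transcript could pass unseen.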
